A study of Mus musculus with 6 samples.

How the data were processed

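ChIP-seq was performed on mouse prostate tumor cells (C57BL/6) with antibodies to FOXA1 and FOXA2, after tamoxifen for 2 weeks or 6 months. Per the labels' protocols, 3 mouse prostates were dissected, fixed with formaldehyde and sheared by ultrasound, and libraries were made with a transposase-based kit and sequenced as paired reads. Whether each library came from its own set of 3 prostates, or whether the 2 antibodies shared chromatin at a time, is not given in the sources used here. The 6 libraries form 6 groups of 1.

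Per the submitters' processing notes, Trim Galore 0.5.0, Bowtie2, deepTools 3.2.1, MACS2 2.1.1, DiffBind 2.12.0, bedtools 2.25.0 and HOMER were used with build mm10; their roles and parameters are not given in the sources used here. The deposited peak lists have the layout of MACS2 and hold 1 library each, so peaks were called per library by the authors. Whether the input libraries served as control is not given in the sources used here. The authors' fold enrichment (a ratio at the summit over the caller's local background), their -log10 of the p-value and of the q-value, and their score, which in the deposited files equals the whole part of 10 times the -log10 q, belong to each peak. The smallest -log10 q in the deposited lists corresponds to a q-value of 0.05. A peak caller finds more peaks in a deeper or cleaner library, so the number of peaks and absence from a list depend on depth and on the precipitation as well as on occupancy. The lists give no read depth.

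Peaks on the chromosomes 1 to 19, X and Y were used and overlapping peaks merged, which joined none; 12, 2, 0 and 3 peaks on unplaced contigs were left out of the lists of Foxa1 at 2 weeks, Foxa1 at 6 months, Foxa2 at 2 weeks and Foxa2 at 6 months. Regions were called shared with an overlap of at least 1 bp. Shares were computed for whole lists and for 10 equal parts ranked by -log10 q, with exact Clopper-Pearson 95% intervals, and set beside 100 random circular shifts of the other list within each chromosome's span. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. Overlap counts were checked against bedtools 2.31.1 and were equal. On simulated data, all 16355 planted overlaps among 54226 regions were recovered, 2000 of 2000 gene assignments matched a direct search, 8 of 200 random lists of 16 genes lay outside the percentile range and 190 of 200 lists with raised region numbers lay above it. The check on lists used region numbers of the 2-week Foxa1 library alone. Percentiles of differences between libraries were not checked in this way.

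Gene positions came from a RefSeq gene table of GRCm38.p6, whose coordinates on these chromosomes are those of mm10, with 21887 protein-coding genes. The table gives gene starts and ends without strand or exons. The planned distance to a transcription start site was therefore replaced by the distance to the nearer gene end, and the planned assignment to the nearest start site by assignment to every gene body that holds the summit, or else to the gene with the nearest end within 100 kb. Exons, introns and untranslated regions were not distinguished. No genome sequence was used here, so the planned scan for 22 motifs, forkhead motifs among them, was not run.

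For genes, lists were limited to the 34942 strongest regions by -log10 q, the length of the shortest long list. All 190 genes of 15 lists fixed before the data were examined were found in the table: luminal and androgen response, basal epithelium, neuroendocrine and neuronal, mesenchymal transition, epithelial and pioneer factors, progenitor markers, AP-1 and Hippo targets, proliferation, signalling receptors, endodermal Foxa targets, tumour suppressors, and markers of stroma, immune cells, endothelium, and seminal vesicle and urothelium. A list's sum was placed among 10000 random lists of protein-coding genes matched in 10 bins of territory, the stretch of genome from which a gene takes regions, and was called outside the range when it lay outside the central 95% of them. This describes these libraries and is not a test of the conditions. The number of list members with a region was placed in the same way, a measure added after the data were examined.

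Named genes followed a rule fixed before the data were examined: in each main comparison the 10 genes with the largest gain and the 10 with the largest loss of regions, the 5 strongest regions of each class, every region of a list of 5 or fewer, 2 to 4 members per gene list with the largest difference, and Foxa1 and Foxa2. Some items that this rule selects are not reported here. Alternatives were a -log10 q or a fold enrichment of at least 5, a reciprocal overlap of 50%, summits within 200 bp, lists of equal length, autosomes only, unmerged peaks, a 5 kb window at gene ends, gene bodies with 10 kb to either side, and full lists. Joining regions less than 1 kb apart and matching random lists on regions per gene were added after the data were examined.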

Results

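Binding of the forkhead pioneer factors Foxa1 and Foxa2 was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse prostate tumor cells of C57BL/6 animals treated with tamoxifen for 2 weeks or for 6 months. The series' title places the work in the progression of prostate cancer. There were 6 libraries, 1 per group: Foxa1, Foxa2 and input at each time. Peak lists of the 4 immunoprecipitated libraries were analysed, and the input libraries were not analysed here. With 1 library per group no difference has a replicate check, so no test between groups was made, and intervals on shares (exact Clopper-Pearson, 95%) cover counting error only. Read depth is unknown from the peak lists. Fold enrichment and -log10 q are the authors' values for each peak and serve here to describe, rank or filter peaks within their own list, and fold enrichment is compared between lists only by rank.

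The Foxa1 list held 54226 regions at 2 weeks and 35869 at 6 months on the chromosomes 1 to 19, X and Y. The Foxa2 list held 1 region at 2 weeks and 34942 at 6 months. Median region width was 472 bp in the 2-week Foxa1 list, 346 bp in the 6-month Foxa1 list and 339 bp in the 6-month Foxa2 list. These lists covered 34.8, 21.6 and 18.2 Mb of the genome. Median fold enrichment was 4.00, 3.43 and 3.75, and median -log10 q was 5.79, 4.37 and 4.51.

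The first comparison asked how far Foxa1 occupied the same sites at 2 weeks and at 6 months. Most Foxa1 regions were listed at 1 time alone: 11825 of the 54226 regions at 2 weeks, 21.8% (interval 21.5 to 22.2%), overlapped a 6-month region, and 12602 of the 35869 regions at 6 months, 35.1% (34.6 to 35.6%), overlapped a 2-week region. Members of the neuroendocrine list such as Prox1, Snap25 and Sox2 held more regions at 6 months, as did Chd7 and Foxa2. The androgen-responsive luminal genes Slc45a3 and Fkbp5 held fewer regions at 6 months than at 2 weeks. Random shifts of the other list along each chromosome gave mean overlaps of 1.65% and 2.60%. With a reciprocal overlap of 50% the shares were 9.57% and 14.5%. Overlap was highest among strong regions. In the strongest 10% of the 2-week list by -log10 q, 48.3% (47.0 to 49.7%) were also called at 6 months, against 12.7% (11.8 to 13.6%) in the weakest 10%. In the 6-month list these shares were 62.5% (60.9 to 64.1%) and 23.4% (22.0 to 24.8%). Even so, 2801 of the 5423 strongest regions at 2 weeks had no counterpart at 6 months. Across the 11825 shared regions, which are not independent replicates, fold enrichment at the 2 times had a Spearman rank correlation of 0.16. Each 2-week region was paired with the first 6-month region it overlapped by position, which need not be the strongest. Another pairing was not tried.

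**Figure D1:**
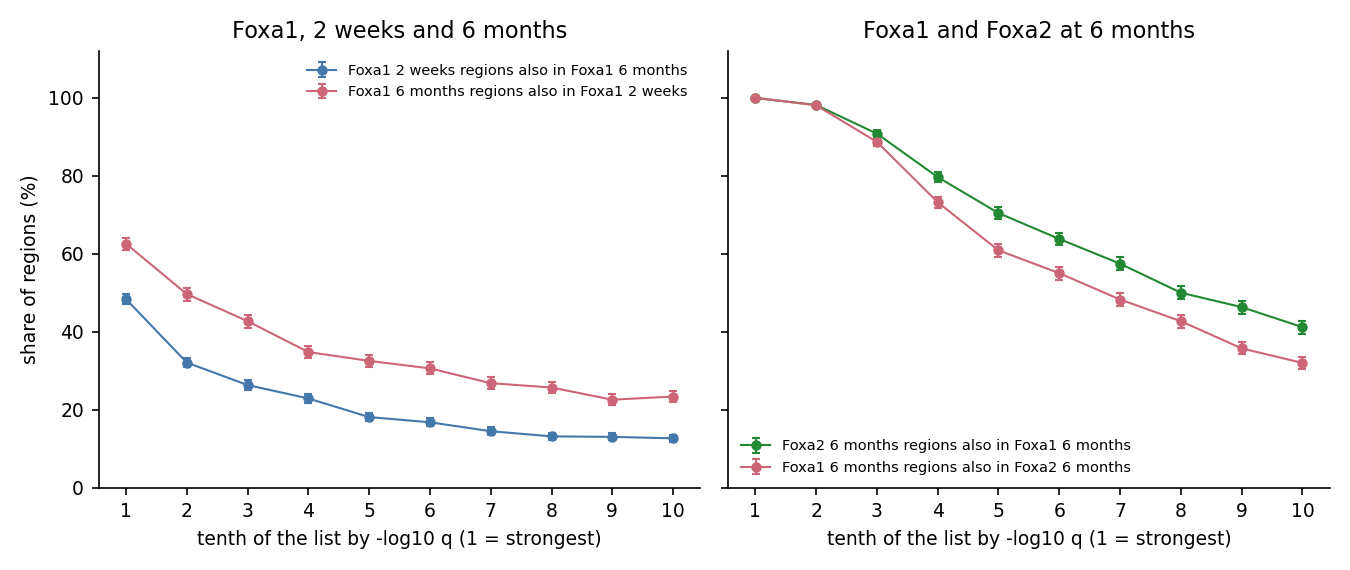
Share of regions that overlap a region of another list (vertical axis, %) in each of 10 equal parts of the list ranked by the authors' -log10 q (horizontal axis, 1 is the strongest), with exact 95% intervals that cover counting error only. Between times the Foxa1 share runs from 48.3% to 12.7% and from 62.5% to 23.4%, while between Foxa1 and Foxa2 at 6 months the strongest parts overlap almost wholly.

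The strongest regions of the 2-week list without a 6-month counterpart lay in Ccdc34 (chromosome 2, 110166458 to 110168798, mm10; fold enrichment 23.1, -log10 q 119), in Pik3cg (chromosome 12, 32186459 to 32189342; fold 22.2), near Nfil3, in Rasgef1a and in Mllt3. The strongest without a 2-week counterpart lay in Tcf7l1, a transcriptional repressor of the Wnt pathway (chromosome 6, 72640249 to 72644642; fold 15.4, -log10 q 85.3), 7.18 kb from Aopep (chromosome 13, 62955193 to 62960861; fold 12.1), in Synrg, and at a pair of sites with no protein-coding gene within 100 kb (chromosome 2, 108671214 to 108676035, and chromosome 17, 9886506 to 9889566). Among regions of both times the strongest were in Cdc42bpa at 2 weeks (chromosome 1, 180041503 to 180043350; fold 25.6) and in Stat4 at 6 months (chromosome 1, 51993016 to 51997973; -log10 q 108).

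To compare genes, each list was limited to its 34942 strongest regions, and each region was assigned to the protein-coding genes that held its summit or else to the gene with the nearest end within 100 kb. Assignment by position does not show which gene a region regulates. Of 21887 genes, 9406 had a Foxa1 region at 2 weeks and 7343 at 6 months, with 5804 genes in common. There were 246 genes with at least 10 more regions at 6 months and 111 with at least 10 fewer. Among regions with a -log10 q of at least 5 these numbers were 20 and 204, and with the full lists 162 and 464. Those lists were of unequal length, with 32416 regions at 2 weeks and 15366 at 6 months, and 54226 and 35869 in full. A shorter 6-month list favours deficits, so these values do not show that the balance reversed. Lists of equal length reach weaker regions at 6 months, which favours excesses. No 2-week region with a -log10 q below 3.91 was kept, whereas the 6-month list reached 1.88 or lower. The balance of 246 and 111 is therefore not settled either. The largest excess at 6 months was at Chd7, a chromatin remodeller (chromosome 4, 8690402 to 8868449), with 11 regions at 2 weeks and 74 at 6 months. Foxa2 itself (chromosome 2, 148042877 to 148046969) had 2 and 51. The calcium channel subunit gene Cacna2d3 had 7 and 59, the mitochondrial carrier gene Slc25a21 had 16 and 61, and 1700113H08Rik had 2 and 42. The adhesion gene Sdk1 had 3 and 42, Grip1 had 9 and 44, the HMG-box gene Tox had 11 and 46, and the homeobox gene Prox1 had 1 and 35. Foxp1, another forkhead gene, had 43 and 86. It had 41 and 34 among regions with a -log10 q of at least 5, where the 6-month list was also shorter (15366 against 32416 regions). The lower count at 6 months therefore does not show a deficit. Nor do 43 and 86 show a clear gain, since they include weaker regions at 6 months than at 2 weeks. Many of these regions lay close together: with regions less than 1 kb apart joined, Chd7 had 10 and 36, Foxa2 had 2 and 18, and Foxp1 had 29 and 33. The numbers of genes with at least 10 more and 10 fewer were then 53 and 98, the reverse of the order without joining.

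The largest deficits at 6 months were at the recombination gene Rad51b (chromosome 12, 79297282 to 79848260), with 48 regions at 2 weeks and 17 at 6 months, and at the death receptor gene Tnfrsf21 (chromosome 17, 43016555 to 43089188), with 30 and 3. Mtus1 had 28 and 3, Dach1 had 26 and 2, and Stxbp6 had 23 and 1. Vps13d (34 and 9), Macrod2 (41 and 16), the polarity gene Pard3b (32 and 8), the homeobox gene Zfhx3 (30 and 9) and the potassium channel gene Kcnma1 (31 and 11) had more regions at 6 months than Mtus1, Dach1 or Stxbp6.

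**Figure D2:**
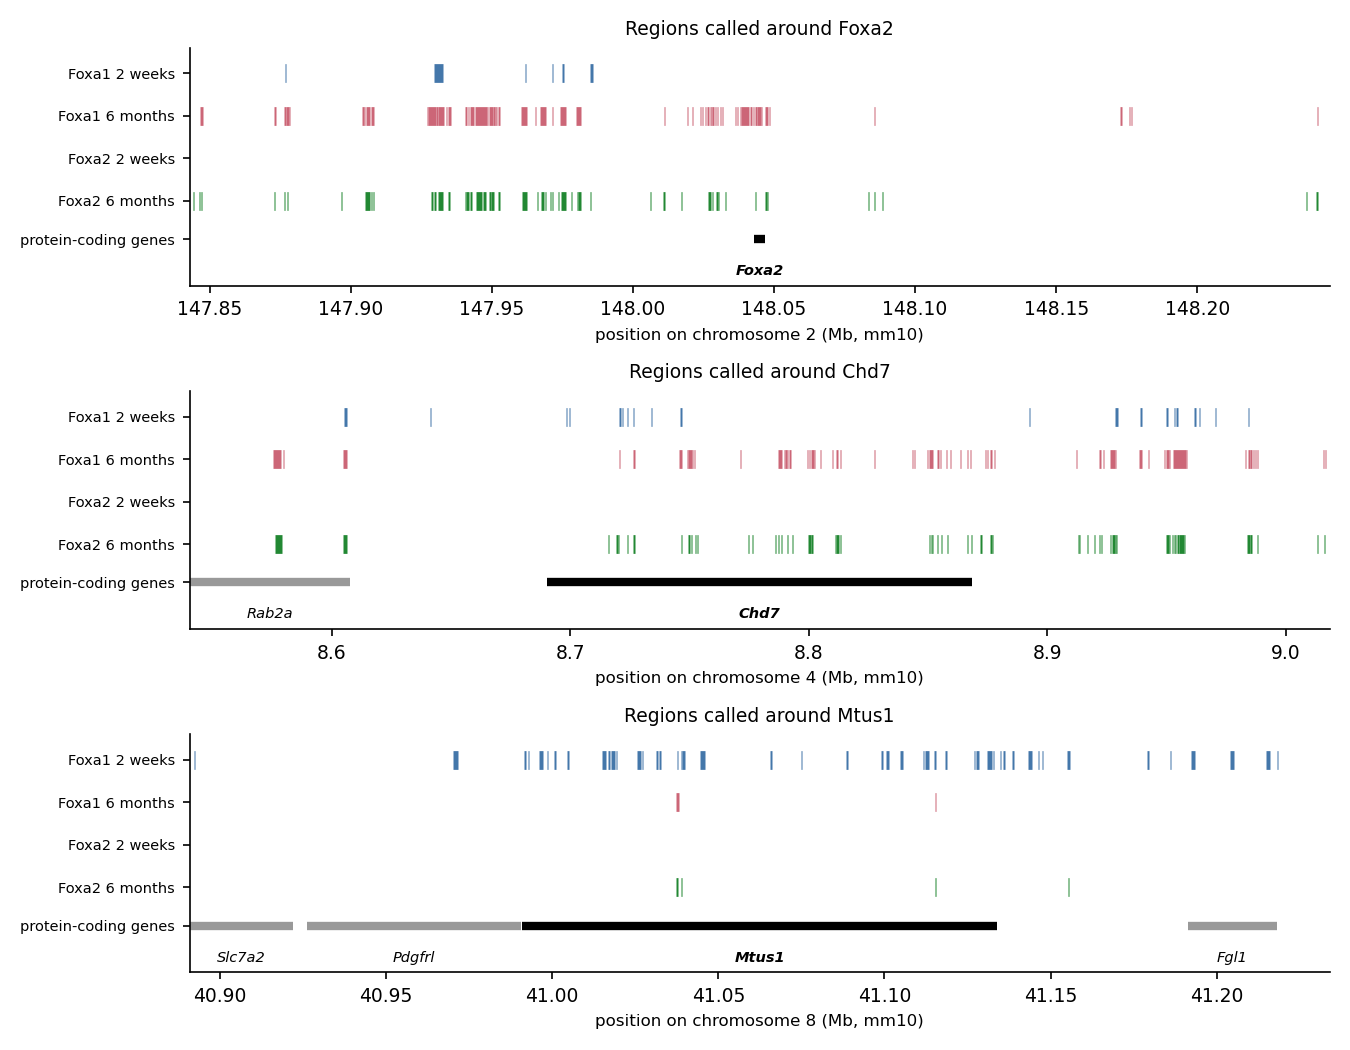
Called regions (colored bars, to scale) of the 4 libraries around Foxa2, Chd7 and Mtus1, with protein-coding genes below and the position on the mm10 chromosome in Mb on the horizontal axis. The full Foxa1 lists hold 6 regions at 2 weeks and 73 at 6 months in the stretch around Foxa2, 25 and 91 around Chd7, and 54 and 3 around Mtus1.

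Gene groups fixed beforehand differed in direction. Members of the neuroendocrine and neuronal list held 27 Foxa1 regions at 2 weeks and 171 at 6 months, a difference above that of all 10000 random lists matched on territory (100th percentile, random range -33 to 50). For regions the list stood at the 1.8th percentile at 2 weeks, with little room to fall, and at the 99.95th at 6 months. The difference of 144 was 64 with regions less than 1 kb apart joined and 47 within 5 kb of gene ends. Of its 24 members, 17 had more regions at 6 months, 4 had fewer and 3 had equal numbers. Prox1 had 1 and 35, Snap25, which encodes a synaptic vesicle fusion protein, had 1 and 23, and Sox2, which encodes a neural and stem cell transcription factor, had 2 and 17. In the luminal and androgen response list, all 18 members had a region at 2 weeks and 11 had one at 6 months, a difference at the 1.21st percentile by a measure added after the data were examined, although the summed regions were 89 and 88 (53rd percentile). Fkbp5, an androgen-induced chaperone gene, had 10 and 1 and Slc45a3 had 6 and 0, whereas Abcc4 had 15 and 29 and Cd24a had 6 and 16. Members without a 6-month region, named after their values were seen, included Pbsn, Hoxb13, Msmb and Steap4. With every member occupied at 2 weeks this measure could only fall, and at 6 months the list still stood high, at the 98.6th percentile for members with a region and the 99.7th for regions. This deficit of members lay at the 4.76th percentile with the full lists and was 0 members within 5 kb of gene ends.

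The list of epithelial and pioneer factors had 137 regions at 2 weeks and 184 at 6 months (98.4th percentile), but its median member had a difference of -0.5, and 8 of its 16 members had fewer at 6 months against 6 with more. Foxa2 made up the excess (2 and 51). Nfib had 27 and 38, Tfap2a had 8 and 18, and Ehf had 21 and 12. Foxa1 itself had 11 and 10. Among regions with a -log10 q of at least 5 the list's sum differed by -43 (5.99th percentile), and with the full lists by -42 (16th percentile). In both, the 6-month list was shorter than the 2-week list. Markers of seminal vesicle and urothelium had 8 regions at 2 weeks and 0 at 6 months (0.31st percentile), from Upk1b (5 and 0), Upk3a (2 and 0) and Svs4 (1 and 0). These genes mark tissue beside the prostate that a dissection can include.

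The other 11 lists lay within the random range. Differences summed to -6 for basal epithelium (26.0th percentile; Dst 11 and 8, Dsg3 1 and 0), -5 for mesenchymal transition (36.6th; Tgfbr2 9 and 3, Tgfb2 5 and 9), -2 for progenitor markers (40.1st; Cd44 13 and 4, Krt7 4 and 11) and -4 for AP-1 and Hippo targets (43.6th; Amotl2 0 and 3, Fosl2 5 and 2). They were -5 for proliferation (27.2nd; Ezh2 4 and 0, Aurka 1 and 0), -11 for signalling receptors (20th; Egfr 13 and 1, Igf1r 12 and 24) and -9 for endodermal Foxa targets (15.1st; Shh 7 and 2, Cdx2 1 and 5). Tumour suppressors differed by 4 (85.9th; Cdkn1b 6 and 8, Cdkn2a 2 and 4), stroma by -7 (19.5th; Dcn 8 and 3, Acta2 2 and 1), immune cells by -3 (33.6th; Cd3e 2 and 0, Itgam 1 and 0) and endothelium by 15 (89.2nd; Vwf 7 and 13, Cdh5 0 and 5). With 15 lists, 0.75 per comparison lie outside the range by chance.

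**Figure D3:**
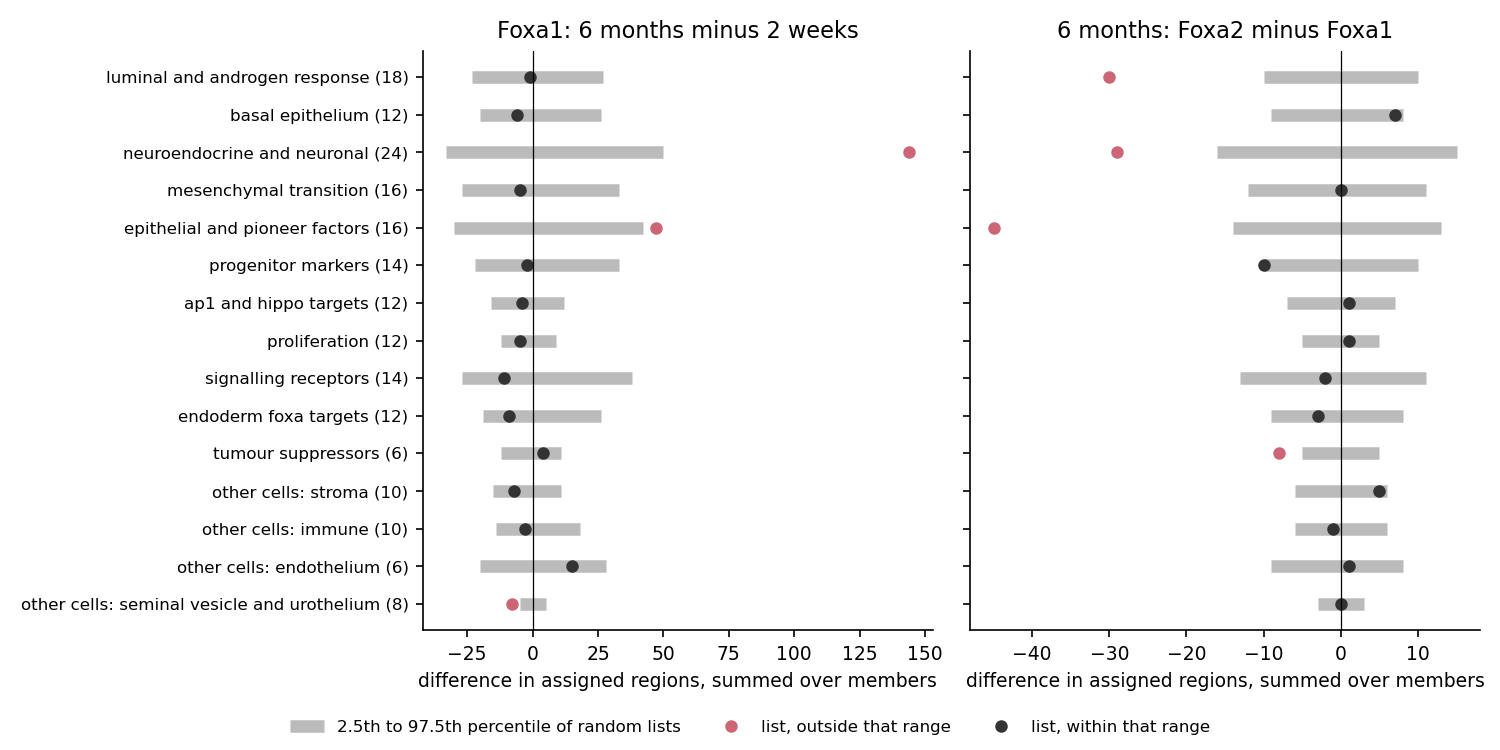
Difference in assigned regions summed over the members of each list (horizontal axis, regions; number of members in parentheses), for Foxa1 at 6 months minus 2 weeks and for Foxa2 minus Foxa1 at 6 months, with the central 95% of matched random lists in gray. The neuroendocrine and neuronal list stands at 144 on the left and at -29 on the right.

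The second comparison set Foxa1 against Foxa2 at 6 months. By an overlap of at least 1 bp, 24372 of the 34942 Foxa2 regions, 69.7% (69.3 to 70.2%), overlapped a Foxa1 region, and 22756 of the 35869 Foxa1 regions, 63.4% (62.9 to 63.9%), overlapped a Foxa2 region, against 1.53% and 1.48% after random shifts. With a reciprocal overlap of 50% these shares were 42.1% and 41%, and with summits within 200 bp 49.8% and 48.6%. In the strongest 10%, 3491 of 3495 Foxa2 regions and 3586 of 3587 Foxa1 regions were shared. In the weakest 10% the shares were 41.2% (39.5 to 42.8%) and 32.0% (30.5 to 33.6%). Regions of 1 factor alone were weak, with a median -log10 q of 3.01 for Foxa2 alone and 2.85 for Foxa1 alone, against 5.47 and 5.69 for shared regions. Their absence from the other list can therefore be a matter of threshold. The Spearman rank correlation of fold enrichment across 22756 shared regions, which are not independent replicates, was 0.53. Each Foxa1 region was again paired with the first Foxa2 region it overlapped by position.

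The strongest region of the Foxa2 list lay 35.9 kb from Chd6 (chromosome 2, 161143598 to 161145777; fold 20.8, -log10 q 92.2) and was shared with Foxa1. The strongest regions of Foxa2 alone included those in Stk4 (chromosome 2, 164133765 to 164134546; fold 5.99, -log10 q 15.3), 15.0 kb from Prkch, 34.5 kb from Ppfia2 and in Dpyd. Those of Foxa1 alone included a region in Gfra1, a receptor of glial cell line-derived neurotrophic factor (chromosome 19, 58323691 to 58324353; fold 4.22, -log10 q 14.8), 1 at 11.9 kb from Six3, 1 at 47.7 kb from Kcnh5 and 1 in Tacc2.

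At the gene level, 7343 genes had a Foxa1 region and 7744 a Foxa2 region, with 6709 in common. Only 4 genes had at least 10 more Foxa2 regions and 10 had at least 10 fewer. The former were the cadherin gene Cdh13 (33 Foxa1 and 45 Foxa2 regions), Auts2 (39 and 51), Fat3 (26 and 36) and the calcium channel gene Cacna1c (10 and 20). Next came Ank3 (19 and 28), Ptprn2 (17 and 26), Tenm2 (31 and 40), Sox5 (33 and 42), Adcy2 (12 and 20) and Cadm1 (31 and 39). Fewer Foxa2 than Foxa1 regions were assigned to Sipa1l3 (28 and 12), Nfib (38 and 23), Slc25a21 (61 and 47), the neural gene Sox1 (21 and 7), Pip5k1b (37 and 25), Kitl, which encodes stem cell factor (26 and 14), Btg2 (20 and 9), Foxa2 itself (51 and 41), Cdkal1 (47 and 37) and Tox (46 and 36). Several of these differences did not hold among stronger regions: with a -log10 q of at least 5 the difference was 0 for Cdh13, Cacna1c and Btg2, 1 for Auts2 and -1 for Sipa1l3. With regions less than 1 kb apart joined, Foxa2 had 18 Foxa1 and 24 Foxa2 regions. For Foxa1 itself the counts were 10 and 11.

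In 4 lists the deficit of Foxa2 against Foxa1 regions lay below the random range. The luminal list differed by -30 (percentile 0; Abcc4 29 and 21, Cd24a 16 and 8), epithelial and pioneer factors by -45 (percentile 0; Nfib 38 and 23, Tfap2a 18 and 10), the neuroendocrine list by -29 (0.055th percentile; Prox1 35 and 28, Sox2 17 and 11) and tumour suppressors by -8 (0.595th percentile; Cdkn1b 8 and 4). With regions less than 1 kb apart joined, epithelial and pioneer factors differed by 5 (68.6th percentile) and the neuroendocrine list by -4 (3.69th percentile). Among regions with a -log10 q of at least 5, the luminal list stood at the 8.96th and tumour suppressors at the 47.6th percentile. The other 11 lists lay within the random range, from -10 for progenitor markers (2.76th percentile) to 7 for basal epithelium (95.4th percentile). Between them stood signalling receptors with -2 and endodermal targets with -3, mesenchymal transition and the seminal vesicle and urothelium list with 0, immune cells with -1, stroma with 5, and AP-1 targets, proliferation and endothelium with 1 each.

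The third comparison concerned Foxa2 over time. At 2 weeks the list held a single Foxa2 region (fold enrichment 6.52, -log10 q 11.7), and at 6 months 34942 regions were listed. That region was in none of the other lists: the nearest region was 30.3 kb away for Foxa1 at 2 weeks, 233 kb for Foxa1 at 6 months and 30.8 kb for Foxa2 at 6 months. The peak list alone does not show whether the 2-week precipitation had worked.

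The fourth comparison asked whether Foxa2 at 6 months lay where Foxa1 had been earlier. Of the 34942 Foxa2 regions, 12843, or 36.8% (36.2 to 37.3%), overlapped a Foxa1 region of 2 weeks, against 2.48% after random shifts, and 15.8% did so with a reciprocal overlap of 50%. Of the 6-month Foxa1 regions, 35.1% overlapped a Foxa1 region of 2 weeks, so the share is not particular to Foxa2. Foxa1 was listed at both times for 10249 (29.3%), at 6 months only for 14123 (40.4%), at 2 weeks only for 2594 (7.42%), and at neither time for 7976 (22.8%). The strongest Foxa2 region with Foxa1 at 6 months only was in Tcf7l1 (chromosome 6, 72640323 to 72642619; fold 16.9), followed by one 7.13 kb from Aopep, one 98.2 kb from Sox11, and one in Synrg. With Foxa1 at 2 weeks only they were in Stk4, near Prkch, in Atp6v0a4 and near Fabp5, and with no Foxa1 region they included regions near Ppfia2, in Dpyd, in Rcor3 and in Kcnq5. Foxa1 regions of 6 months that had been listed at 2 weeks carried Foxa2 in 77.9% (77.2 to 78.6%), and those listed only at 6 months in 55.6% (55.0 to 56.3%). The latter were weaker, with a median -log10 q of 3.91 against 5.69. In the strongest 10% of Foxa1 regions, 2243 of 2243 and 1343 of 1344 carried Foxa2, and in the weakest 10% the shares were 42.7% (39.3 to 46.1%) and 28.8% (27.1 to 30.5%).

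**Figure D4:**
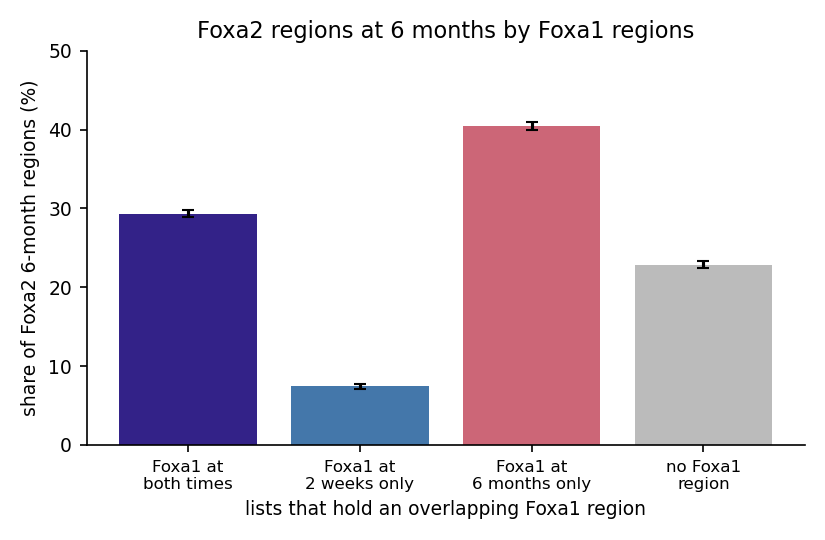
Share of the 34942 Foxa2 regions at 6 months (vertical axis, %) that overlap a Foxa1 region at both times, at 2 weeks only, at 6 months only or at neither time, with exact 95% intervals that cover counting error only. The class with Foxa1 at 6 months only is the largest, at 40.4%.

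By position, summits of all 3 long lists lay mostly within gene bodies. Most were away from gene ends, though more lay near them than among uniform positions. Summits inside a protein-coding gene made up 56.0% (55.6 to 56.4%) of Foxa1 regions at 2 weeks, 57.0% (56.5 to 57.5%) at 6 months and 57.1% (56.6 to 57.7%) of Foxa2 regions, against 38.4% of uniformly placed positions. Summits within 1 kb of either end of a gene made up 4.79% (4.61 to 4.97%), 4.72% (4.50 to 4.94%) and 4.86% (4.64 to 5.09%), against 2.94%. Foxa1 regions of both times lay near gene ends more often, in 6.49% of 2-week regions, than those of 2 weeks only, in 4.31%, or of 6 months only, in 3.81%. More than 100 kb from any protein-coding gene lay 11.7% of Foxa1 regions at 2 weeks, 14.4% at 6 months and 14.0% of Foxa2 regions, against 29.2% of uniform positions.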

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

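All tests in this part were chosen after the results were seen. The numbers of Foxa1 and Foxa2 regions went opposite ways between the 2 times: 6 months minus 2 weeks came to -18357 for Foxa1 and 34941 for Foxa2. With 1 library per group this difference was not tested.

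A first technical explanation for the single Foxa2 region at 2 weeks is that the precipitation or library failed. For the long 6-month Foxa2 list, one is that the antibody also pulled down Foxa1, which goes with the near-complete overlap of the strongest 6-month regions. Of the 3495 strongest 6-month Foxa2 regions and of the 5423 strongest 2-week Foxa1 regions, 0 overlapped the 2-week Foxa2 list. A list of 1 region fixes this outcome, so these overlaps add nothing to the length of that list. A failed precipitation and an absent protein at 2 weeks cannot be told apart. An antibody that also pulled down Foxa1 would have given many 2-week regions in a precipitation that worked, since the 2-week Foxa1 list held 54226. It stays open because the lists do not show whether that precipitation worked. Absence of Foxa2 at 2 weeks, a biological difference between the times that the design names, is untested.

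Outside the chromosomes used, the 2-week Foxa1 list held 12 peaks on unplaced contigs, 9 of them on 1 contig assigned to chromosome 4. They are given here only because no comparison used them. The 6-month Foxa1 and Foxa2 lists held 2 and 3, no library serves as a control for these peaks, and nothing is concluded from them.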

How the results depend on the processing

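No paired analysis was possible because each group has 1 library. Joining regions less than 1 kb apart and matching random lists on regions per gene were chosen after the data were examined. The motif alternatives were not run, since no genome sequence was used here. Of 332 alternative values, 165 stayed within the interval, within 1.5 times the count, or on the same side of the percentile range. Fewer regions under a stricter threshold or overlap rule follow from how the alternative is made. For other shifts below, the cause was not tested. Weak regions near the threshold and an unknown read depth limit every statement on absence.

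With a -log10 q of at least 5, 32416 Foxa1 regions were left at 2 weeks and 15366 at 6 months, and 15093 Foxa2 regions at 6 months. With a fold enrichment of at least 5 these were 17410, 5421 and 7046, and the single 2-week Foxa2 region passed both. The share of 2-week Foxa1 regions also called at 6 months was 18.3% with the q threshold, 13.1% with the fold threshold, 9.57% with reciprocal overlap of 50%, 15.7% with summits within 200 bp and 26.2% with lists of equal length. In the same order, the reverse share was 39.2%, 41.5%, 14.5%, 23.8% and 29.6%, the share of 6-month Foxa2 regions also called for Foxa1 was 73.0%, 65.0%, 42.1%, 49.8% and 68.9%, the reverse 68.6%, 82.3%, 41%, 48.6% and 64.2%, and the share of Foxa2 regions with Foxa1 at 2 weeks 40.0%, 38.2%, 15.8%, 25.6% and 30.6%. On autosomes alone both overlap comparisons stayed within their intervals. The share near gene ends with the fold threshold was 4.42% for Foxa1 at 2 weeks and 4.06% at 6 months, and within 5 kb it was 18.6%, 16.9% and 17.2% for Foxa1 at 2 weeks, Foxa1 at 6 months and Foxa2.

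The members of all gene lists with a region within 5 kb of a gene end were 63, 60 and 63 in these libraries, against 127, 104 and 104 in the main assignment. Genes with at least 10 more Foxa1 regions at 6 months were 20 with the q threshold, 3 within 5 kb of gene ends, 162 with full lists and 53 with close regions joined. Genes with at least 10 fewer were 204 with the q threshold, 73 with gene bodies and 10 kb, 0 within 5 kb and 464 with full lists.

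The neuroendocrine list's excess of Foxa1 regions at 6 months stood at the 100th percentile in all 6 alternatives, and the seminal vesicle and urothelium deficit stayed below the 2.5th. Members of the neuroendocrine list with a region stood at 96.6 with full lists. The luminal deficit of members stood at 9.13 with gene bodies and 10 kb, 4.76 with full lists and 78.5 within 5 kb. Epithelial and pioneer factors stood at 5.99 with the q threshold, 91.4 with gene bodies and 10 kb, 16 with full lists, 51 when matched on regions per gene and 7.26 with close regions joined. For Foxa2 against Foxa1, the luminal list stood at 8.96 and tumour suppressors at 47.6 with the q threshold, and with close regions joined the neuroendocrine list stood at 3.69 and epithelial and pioneer factors at 68.6. Of 54 list percentiles under alternatives, 41 stayed outside the range on the same side.

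Of the 20 named genes of each main comparison, 14 kept the sign of their difference under all 5 counting alternatives between times and 8 between factors. Sign changes between times were Foxp1 with the q threshold (-7), where the 6-month list was shorter, and Zfhx3 within 5 kb (1). Between factors they were Ptprn2 (-1) and Slc25a21 (1) within 5 kb, Sox5 with the q threshold (-1) and Foxa2 with close regions joined (6). The others had a difference of 0 in some alternative.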

Other observations

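Among the tests in this part, those on copy number, territory, cell mix and gene families were chosen after the results were seen. Foxa1 regions of 6 months formed dense clusters. The 20 windows of 250 kb with the largest excess, chosen after their values were seen, held 86 Foxa1 regions at 2 weeks, 721 at 6 months and 612 Foxa2 regions at 6 months. They include Chd7 (7 and 70 Foxa1 regions), the Foxa2 gene (0 and 39) with the window beside it that holds no protein-coding gene (4 and 44), Prox1 (1 and 35), Pex5l on chromosome 3, 33000001 to 33250000 (0 and 32), Snap25 (3 and 34), Id4 (2 and 31), Foxp1 (9 and 34) and Sox1 (1 and 25). Their regions were of ordinary strength, with a median at the 46.7th percentile of -log10 q in the 6-month list, and 56.4% overlapped a Foxa2 region against 64.4% elsewhere.

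The windows with the largest deficit at 6 months held Mtus1, Fgl1 and Pcm1 (31 and 3), Tnfrsf21 (29 and 3), Pygb and Gins1 (27 and 2), Prkci and Phc3 (24 and 1), Nfil3 (22 and 2), Nfia (22 and 2), Magi1 (24 and 4), the endothelin gene Edn1 (21 and 3), Etv6 (20 and 3) and Piezo2 (17 and 1). Chromosome X held 1.41% (1.31 to 1.51%) of Foxa1 regions at 2 weeks, 0.664% (0.582 to 0.753%) at 6 months and 0.607% (0.528 to 0.694%) of Foxa2 regions. Of the 763 Foxa1 regions of 2 weeks on chromosome X, 9.96% (7.93 to 12.3%) were also called at 6 months.

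For the dense clusters, broad 2-week regions split into narrow pieces would leave the covered length alike, but it was 6.53 times as long at 6 months in the median of 17 windows with any 2-week region, although with regions less than 1 kb apart joined the 20 windows held 72 and 312. A copy number gain over megabases would also raise windows 500 kb to 1 Mb away, where the median difference in 80 windows was 3.33% of the clusters' median excess of 30 regions, against a bound of 10%. It cannot be told apart from a local gain, since the quartiles ran from -2 to 3 regions, 27 of 80 windows reached the bound, and the windows together held 356 regions at 2 weeks and 433 at 6 months (ratio 1.22). A bootstrap interval of the median (0 to 2), computed after those values were seen, does not settle it. A shared property of the 6-month chromatin or input, which would affect both factors alike, and the tamoxifen time were not tested as causes.

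For the neuroendocrine list, gene territory does not account for the excess, since the list stood at the 100th percentile of lists matched on it. That is the percentile by which the excess was found, so it adds no further evidence. A gain of weak regions alone is argued against by the 100th percentile among regions with a -log10 q of at least 5, where the sum differed by 36. Without its 3 members of largest difference the list stood at the 99.9th percentile. A different mix of cells at 6 months cannot be told apart from a change within cells, because region lists do not measure cell numbers. The stromal list stood at the 19.5th percentile and the endothelial list at the 89.2nd, but such lists would move only if their cells carried Foxa1. The seminal vesicle and urothelium list, with 8 regions at 2 weeks and 0 at 6 months, stood at the 0.31st, which goes with a different tissue mix. The tamoxifen time, which the design names, stays open as untested without replicates.

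A further hypothesis, formed after the windows were seen, was that 6-month Foxa1 regions gather at developmental transcription factor families. The 196 members of 12 families held 391 regions at 2 weeks and 633 at 6 months (99.99th percentile) and among them the Sox family (57 and 146; 10 members with more, 3 with fewer) lay above the central 95% of matched lists. The Fox family did so too (145 and 233), but 8 of its members had more and 16 fewer, and Foxa2 and Foxp1 account for its excess. Foxp1 differed by -7 among regions with a -log10 q of at least 5, where the 6-month list was shorter. Yet 48 members had more, 48 had fewer and 100 had equal numbers, and the 178 members not named elsewhere, to which the test was limited after that value was seen, stood at the 93.2nd percentile, with 37 having more and 44 fewer. The excess thus lay in a few genes, among them Foxn3 (11 and 38), Sox6 (12 and 36) and Pax9 (0 and 9), and a general gain at such families could not be shown.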
